A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

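Rice seedlings were pregerminated at 30 °C for 5 days and grown at 25 °C with 14 h of light and 10 h of dark for 14 days, per the labels' protocols. The leaves were sprayed with rust spores in oil or with oil, and inoculated plants were kept in the dark at 100% relative humidity for 24 h. Total RNA was purified, and biotin-labelled cRNA was made from 5 ug of it and hybridised to Affymetrix rice arrays, per the labels' protocols. The deposited values are the authors' intensity of each probe set on a linear scale, computed with MAS5 per the submitters' processing notes, which give no version. The MAS5 algorithm subtracts a local background and scales each array to a target, and a trimmed mean of 500 was found on each of the 6 arrays. No detection calls were used here, so dim probe sets were left out by brightness. MAS5 signals near the background vary widely on the log scale, and this limits the precision for dim genes. The number of arrays, 3 per group, limits it for all genes.

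The 6 value columns were matched to samples by their labels, and 0 columns with values per sample were left unmatched. The value table held 57381 probe sets, of which 123 were controls. Of the other 57258, the platform annotation listed exactly 1 gene for 22436, several for 95 and none for 34727, and no gene was named from a probe set with several. The 17905 genes were all found in the RefSeq gene table of assembly ASM3414082v1, and 2453 of them had a name other than a number or clone. Old symbols were updated through the gene identifiers. The table of that assembly was used for names and for which genes neighbour one another, and no positions are printed.

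Signals were turned to log2 with no further normalization, since MAS5 scales arrays. Controls and probe sets whose mean log2 signal lay under the 40th percentile were left out, which was a mean log2 signal of 4.55. A gene with several probe sets was represented by the brightest, and probe sets without exactly 1 gene were kept as features of their own. This left 30903 features, of which 15671 were genes and 2164 named genes. Rust was compared with mock by lmFit and eBayes with trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is rust minus mock, and its standard error is the moderated one of limma. Exact permutation tests, Fisher's test and the figures were made with Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and array weights used statmod 1.5.0. In simulated data each of 30903 features took the mean spread of features of like brightness, with independent noise. The 200 changed genes lay above the median brightness. There limma recovered 20 genes changed 2-fold, 187 changed 4-fold and 200 changed 16-fold, with 1, 9 and 9 false calls. Features of like brightness shared 1 spread there, which real genes do not, so these counts can overstate the power for real genes of any brightness. They do not give the power for dim genes or for genes that vary more than others of like brightness.

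Before the data were examined, 33 gene lists were fixed by patterns and locus numbers. The annotation turned out to hold symbols only, so the lists were matched by symbols and synonyms, which were written after the form of the annotation was seen and before any test. A symbol alone does not show what a gene encodes, so a list can hold genes of another kind. Members without a usable symbol were left out. Lists with at least 5 measured genes, 30 in all, were tested with camera (preset correlation 0.01) and Benjamini-Hochberg adjustment over the lists, with an estimated correlation and fry as alternatives. The list of UDP-glycosyltransferases matched 0 genes, and those of NB-LRR proteins and the Calvin cycle, with 1 and 4 measured genes, were not tested. The other cell type lists were dividing cells, root tissue and pollen and flower tissue, beside a list of conserved eukaryotic genes for RNA of the fungus.

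The rule for named genes, also fixed before the data were examined, took the largest changes among genes past the threshold, the leading members of each list, and 12 genes whatever their result. With 0 genes past the threshold, the lists gave up to 2 members each, those with the largest absolute log2 fold change. Of the 12 genes, the tables identified 7 and 6 were tested. PR1a, PR1b, WRKY45 and the naringenin methyltransferase were not matched by symbol, the gene the tables call PAL is not the locus that was fixed, and KSL4 was too dim to be tested. The rule gave 67 genes. The genes described one by one, those drawn in the plot of single genes and the lists followed through every alternative were picked from these after their values were seen. The alternatives were run on all 67, but a gene had no value where an alternative held no feature for it. Genes outside the rule are said to be so where they appear.

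The alternatives were quantile normalization, centring on the median, no filter and a filter at the 60th percentile, a pseudocount of 11.8 signal units, eBayes without trend or with a robust prior, array weights, the mean of a gene's probe sets, every probe set as its own feature, probe sets ending in x or s left out, a replicate block, each array left out in turn, and thresholds of 0.01 and of a 2-fold change. The 10 ways to part the 6 arrays into 3 and 3 were also run through both tests. Groups of arrays noticed in the data entered no test in the Results, which give the values of such arrays 1 by 1 and results without 1 array. The closing part used sets of genes picked because they parted a noticed group of arrays, or 1 array, from the others. It tested their place in the gene order, the other genes of the stretches formed for rust 1 and rust 2, and technical causes for rust 3 with mock 2. The gap of 2 on the log2 scale, the signal floor of 300 and the window of 50 genes used there were chosen after the ways of parting the arrays had been explored. The test of gene order drew 10000 random sets, and on simulated sets of 21 genes it found 20 of 20 clustered sets and 0 of 20 scattered ones.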

Results

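Leaves of Japonica rice (Oryza sativa) were profiled 24 h after pressure-spraying with spores of wheat leaf rust, Puccinia triticina, carried in Soltrol oil, or with the oil alone. Wheat leaf rust infects wheat and is a non-host pathogen of rice. The series' title and design pose the question whether such an inoculation changes the transcripts of the leaf. There were 3 arrays of rust-sprayed leaves and 3 of oil-sprayed leaves, called mock here, each stated by the submitters to be a biological replicate. The signals of every array were on 1 scale, with a mean of 500 after trimming 2% of the probe sets at each end. Median signals lay between 40.7 and 50.8 on 5 arrays and at 101 on rust replicate 3, where the 25th percentile was 29.9 against 7.26 to 10.7 elsewhere. Across probe sets, which are not independent replicates, rust 3 had a mean correlation of 0.86 with the other rust arrays, and the other 5 arrays had 0.90 to 0.93 with the rest of their own group.

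**Figure D1:**
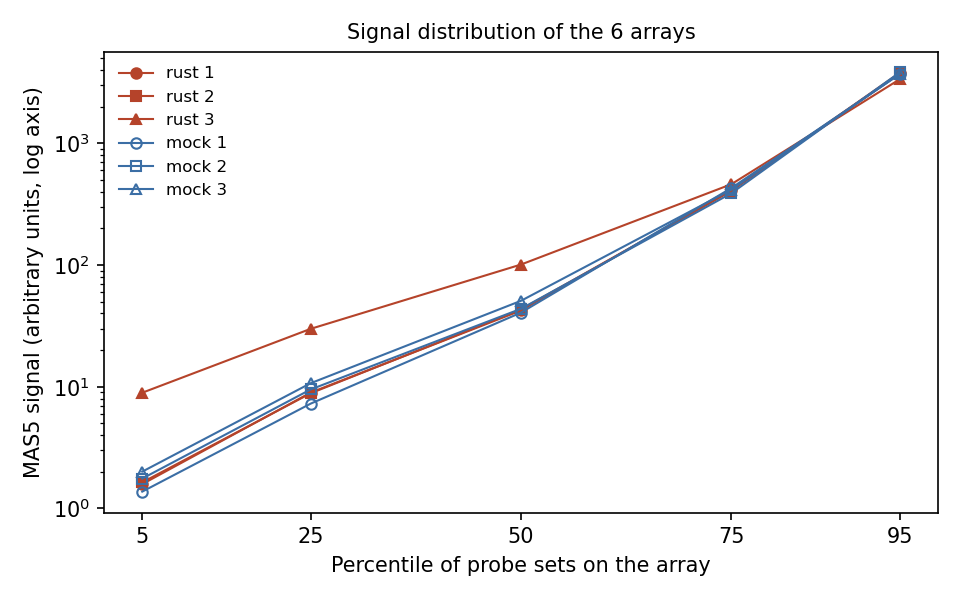
Signal at the 5th, 25th, 50th, 75th and 95th percentile of the probe sets (horizontal axis) on each of the 6 arrays, in arbitrary MAS5 units on a log axis, with filled red symbols for rust and open blue symbols for mock. The median of rust 3 was 101, against 40.7 to 50.8 on the other 5 arrays, and the upper percentiles lay close together.

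The comparison of rust with mock asked which leaf transcripts differed after the non-host spores. By a set test with a preset correlation between genes, the list of jasmonate synthesis and JAZ repressors of jasmonate signalling rose and that of chlorophyll synthesis fell, and neither passed with an estimated correlation (adjusted p = 0.729 for both). By the same test the lists of protein folding in the endoplasmic reticulum and of ribosomal proteins rose, and neither passed with an estimated correlation (adjusted p = 0.795 for both). No single gene passed the test. PBZ1 and the chitinase genes chia4a and Cht4 differed more within the groups than between them.

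Of 30903 features tested, 0 passed an adjusted p of 0.05 with limma, and the smallest adjusted p was 0.209. At an unadjusted p under 0.05, 1118 features were higher and 1015 lower after rust, against 1545 of both kinds together by chance. With each array centred on its median these numbers were 761 higher and 1330 lower. The median log2 fold change of all features was 0.06 as deposited, -0.04 after quantile normalization and -0.07 after that centring, and the median standard error was 0.44. In 12.8% of the features every rust array lay above or below every mock array, where chance gives 10%. Other ways to part the same 6 arrays into 3 and 3 reached 14.6% and 2404 features at an unadjusted p under 0.05, both with rust 1, rust 2 and mock 1 together, against the 2133 of rust against mock. Without rust 3, 20 features passed, 1 higher and 19 lower, and without mock 2, 1 passed.

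Of the 31 measured genes for jasmonate synthesis and JAZ repressors, 25 were higher and 6 lower after rust, with a median log2 fold change of 0.47, and the list rose (camera adjusted p = 0.000662). With an estimated correlation between the genes the list did not pass (adjusted p = 0.729). It also passed in 4 of the 9 other ways to part the arrays into 3 and 3, in 2 of them with a smaller adjusted p, the smallest being 3.23e-08 with rust 1, rust 2 and mock 3 together. AOS1 encodes allene oxide synthase, the enzyme that commits lipid hydroperoxides to jasmonate. Its log2 fold change was 1.09 ± 0.39 (SE, n = 3 against 3, limma adjusted p = 0.696), and its signals of 1480, 1918 and 2188 after rust lay above those of 480, 998 and 1345 in mock. OPDAR1, a 12-oxophytodienoate reductase, had a log2 fold change of 2.77 ± 0.91 (limma adjusted p = 0.696). Its signals of 2598, 2281 and 4134 after rust lay above those of 335, 112 and 2080 in mock, with rust 2 close to mock 3. Without mock 1 AOS1 had 0.67, and without mock 2 OPDAR1 had 1.80. JAZ5, one of the repressors, had a log2 fold change of 3.53 ± 1.32 (limma adjusted p = 0.696). It was at 1960 and 2332 on rust 1 and rust 2 and at 351 on rust 3, and at 261, 11.02 and 360 in mock. Without mock 2, the lowest of these, its log2 fold change was 1.93. The 25th percentile of mock 2 was 9.50, so the size of the fold is not exact, and with a pseudocount it was 3.17. In 8 of the 31 genes all rust arrays lay above all mock arrays, where chance gives 5%. Of all 30903 features, 2087 did so. The genes of the list are not independent, with an estimated correlation of 0.28. Without mock 2 the median of the list was 0.26. The genes' median deviation from their mean over the 6 arrays was 0.11, 0.44 and 0.21 on the rust arrays and -0.37, -0.56 and 0.19 on the mock arrays, so mock 3 lay above rust 1. The call was lost when rust 2 was left out (adjusted p = 0.107).

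Of the 14 measured genes of chlorophyll synthesis, 11 were lower and 3 higher, with a median log2 fold change of -0.31, and the list fell (camera adjusted p = 0.0420). With an estimated correlation the list did not pass (adjusted p = 0.729). CAO, the chlorophyllide a oxygenase that makes chlorophyll b, was below every mock array in all rust arrays, with a log2 fold change of -1.10 ± 0.34 (limma adjusted p = 0.696). CHLP, the geranylgeranyl reductase that supplies the phytol tail, had -1.10 ± 0.47, and its rust 1 signal of 4999 lay within the mock range of 3986 to 5852. Without rust 1 it had -1.69 and without rust 3 it had -0.70. Among the 8 genes for photosystems and light harvesting, 6 were lower and 2 higher, and the list did not pass (camera adjusted p = 0.0717, 0.729 with an estimated correlation). It passed with quantile normalization (0.0284), no filter (0.00829), the replicate block (0.0205) and without rust 1 (0.00148). Its median of -0.24 was -0.12 without rust 2 and -0.38 without rust 3. The largest differences there were those of the chlorophyll a/b-binding proteins RCABP69, with a log2 fold change of -2.33 ± 0.75, and RCABP89, with -1.49 ± 0.62. The probe sets for RCABP69 and for RBCS, described next, can also bind related transcripts. All 4 measured Calvin cycle genes were lower, among them the Rubisco small subunit gene RBCS with -1.69 ± 0.74 and the fructose bisphosphatase gene CFBP1 with -1.04 ± 0.45, and this list was too short to test. RBCS was at 5221 on rust 1, above the mock values of 3474 to 5042, and at 511 and 963 on rust 2 and rust 3. Without rust 1 the log2 fold changes of RBCS and RCABP89 were -2.66 and -2.25, that of RBCS was -0.98 without rust 2, and that of CFBP1 was -0.65 without mock 1. Rust 1 did not share the lower level of the chlorophyll list. The median deviation of its genes was 0.15 there, -0.24 and -0.22 on rust 2 and rust 3, and 0.42, 0.03 and -0.03 on the mock arrays. Without rust 1 the adjusted p was 0.000930. The chlorophyll call was lost without rust 2 (adjusted p = 0.107), without rust 3 (0.286) and without mock 1 (0.349). It was also lost with quantile normalization (0.0578), centring (0.0512), no trend (0.0856), array weights (0.0887) and probe sets ending in x or s left out (0.0643). With fry, another set test, none of the 4 lists that passed with camera did so (adjusted p = 0.615 for each).

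Protein folding genes of the endoplasmic reticulum were higher in 17 of 19 cases, with a median log2 fold change of 0.29, and the list rose (camera adjusted p = 0.0494). With an estimated correlation it did not pass (adjusted p = 0.795). BZIP50, a transcription factor of the unfolded protein response, had a log2 fold change of 1.20 ± 0.52, and PDIL2-3, a protein disulfide isomerase, had 0.70 ± 0.43, which was 0.25 without mock 2. Ribosomal protein genes were higher in 23 of 26 cases, with a median of 0.17, and the list rose with the same adjusted p of 0.0494. It did not pass with an estimated correlation either (adjusted p = 0.795). RPS26 and rps20, with log2 fold changes of 0.66 ± 0.26 and 0.45 ± 0.18, were above every mock array in all rust arrays, and RPS26 had 0.41 without mock 2. The probe sets for rps20 and PDIL2-3 can also bind related transcripts. Rust 3 did not share the higher level of either list. The median deviation of the folding genes was 0.17, 0.33 and -0.19 on the rust arrays and -0.07, -0.43 and 0.01 on the mock arrays. That of the ribosomal genes was 0.12, 0.24 and -0.06 against -0.06, -0.28 and 0.04. Without rust 3 the adjusted p values were 0.000860 and 0.000518. Both calls were lost without mock 2 (adjusted p = 0.372 for both), without rust 1 (0.244 and 0.285) and without rust 2 (0.444 and 0.440). The medians were then 0.12 and 0.07 without mock 2 and 0.16 and 0.10 without rust 2. Both calls were also lost with centring on the median (0.175 and 0.573), no filter (0.0704 and 0.161), a pseudocount (0.0546 for both), no trend (0.156 and 0.224), the mean of probe sets (0.0535 and 0.0536) and the replicate block (0.0802 and 0.126). With centring the medians were 0.16 and 0.05.

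**Figure D2:**
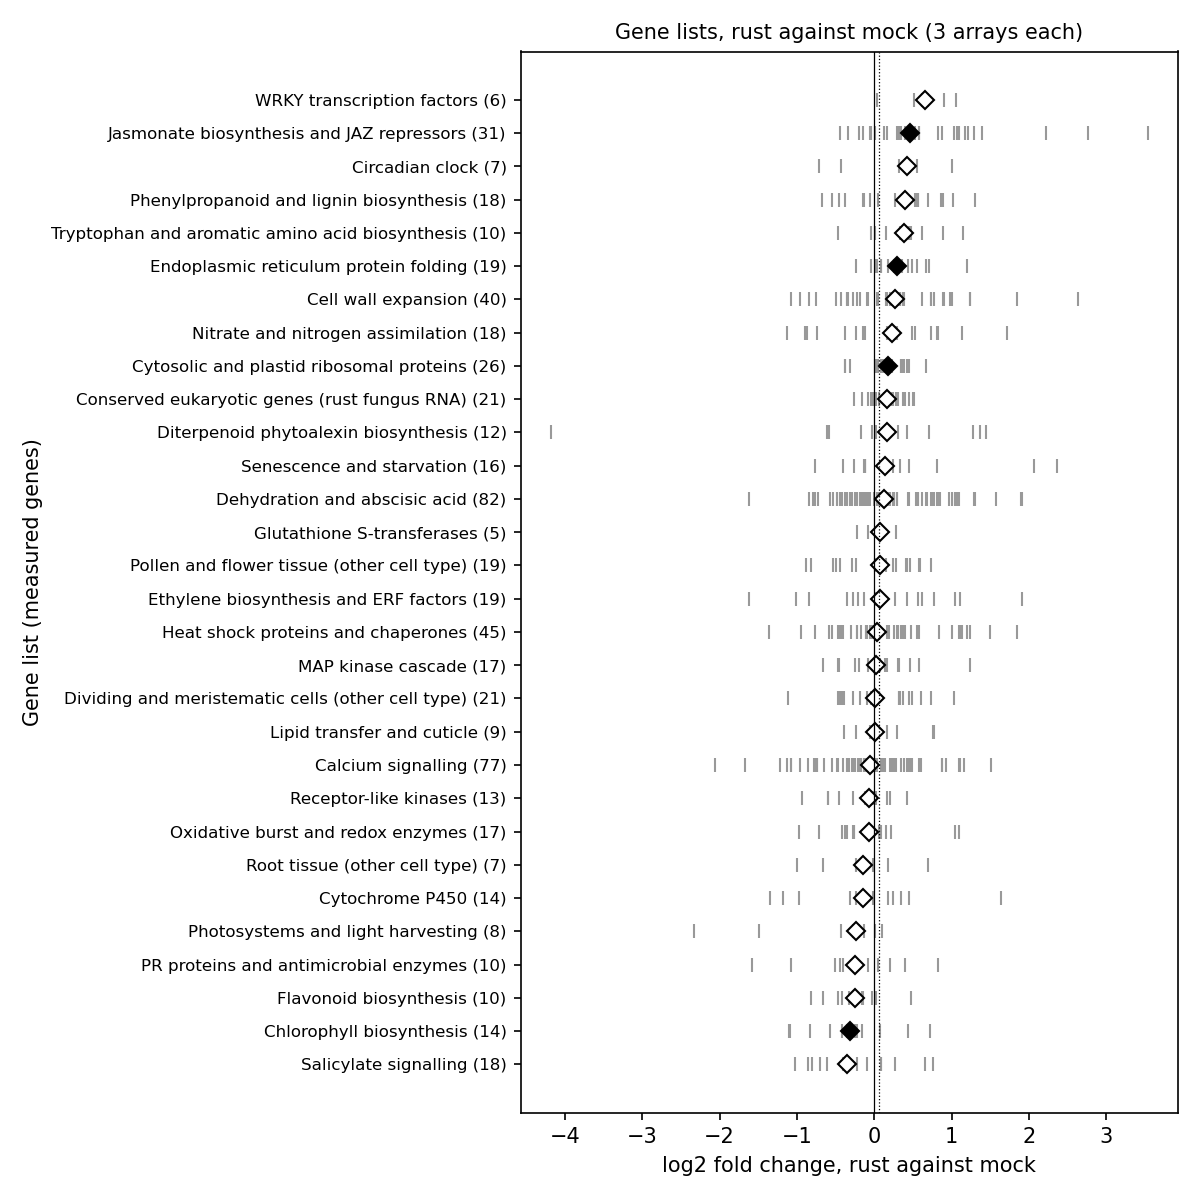
The log2 fold change of rust against mock (horizontal axis) for the 30 tested gene lists (vertical axis), with a grey tick for each gene and a diamond for the median of the list, filled for the 4 lists past the camera threshold. The solid line marks 0 and the dotted line the median of all features, 0.06. The jasmonate list stood at 0.47 and the chlorophyll list at -0.31. Scaling turned the sign of list medians near 0, as for heat shock proteins, -0.01 after quantile normalization.

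Pathogenesis-related and antimicrobial genes did not pass as a list. Of 10 measured, 4 were higher and 6 lower, with a median log2 fold change of -0.25 (camera adjusted p = 0.711). Single arrays set the sign of this median, which was 0.74 without rust 3 (adjusted p = 0.0989), 0.27 without mock 1, 0.21 without mock 3 and -1.04 without mock 2 (0.105). PBZ1, which encodes a PR10 protein, was at 18854 and 18817 on rust 1 and rust 2 but at 265 on rust 3, and at 16960 and 18891 on mock 1 and mock 3 but at 854 on mock 2. Its log2 fold change was -0.51 ± 1.79 (limma adjusted p = 0.965). The chitinase genes chia4a and Cht4 were also lowest on rust 3 and mock 2, with log2 fold changes of -1.58 ± 1.50 and -1.07 ± 1.09. Without rust 3 these became 0.42 and 0.33, and that of PBZ1 became 1.54. All 6 WRKY transcription factor genes that were matched by symbol were higher, with a median of 0.65, and the list did not pass (camera adjusted p = 0.171). These need not stand for the whole family. The median was 0.43 without rust 1 and 1.09 without mock 3. WRKY71 had a log2 fold change of 0.90 ± 0.38. WRKY62 and WRKY76, with 1.05 ± 1.36 and 0.51 ± 0.97, were both lowest on mock 2 and turned to -0.55 and -0.61 without it.

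Genes of diterpenoid phytoalexin synthesis, which make the antimicrobial compounds of rice leaves, went both ways. There were 7 higher and 5 lower of 12, and the median of 0.16 and the mean of -0.01 had opposite signs (camera adjusted p = 0.932). The median was -0.12 after quantile normalization, and it ran from -0.33 without mock 2 to 0.58 without rust 3. CPS2, a diterpene cyclase of this pathway, had signals of 4.79, 5.18 and 25.2 after rust and of 302, 192 and 64.1 in mock. Its log2 fold change was -4.18 ± 0.91 and did not pass (limma adjusted p = 0.645). Over the list alone the limma adjusted p was 0.0212, which does not account for the number of lists searched. These rust signals lay below the 25th percentile of their own arrays, at 8.94, 8.83 and 29.9, so the size of the fold is not exact, and with a pseudocount it was -2.95. CPS4, the cyclase of the momilactone branch, had 0.30 ± 1.12, with -0.92 without mock 2, 1.09 without rust 3 and 0.19 with a pseudocount, and KS10 had 1.44 ± 0.60. In phenylpropanoid and lignin synthesis 11 of 18 genes were higher, with a median of 0.40 (camera adjusted p = 0.711). Mock 2 set this sign, since the median was -0.24 without it, with a test direction of down (adjusted p = 0.363). It was 0.21 without rust 2, 0.70 without mock 3 and 0.17 after quantile normalization. The genes there with the largest differences were 4CL5, a 4-coumarate-CoA ligase, with 1.30 ± 0.56, and CAD2, a cinnamyl alcohol dehydrogenase, with 1.02 ± 0.63. Without mock 2 CAD2 had only 0.21, without mock 1 it had 1.60, and 4CL5 had 2.02 without mock 3. The flavonoid list, matched by symbol alone, was lower in 8 of 10 genes, with a median of -0.25 (camera adjusted p = 0.181), or -0.10 without rust 1. The symbols do not show that each of these genes makes flavonoids. Tryptophan and aromatic amino acid synthesis was higher in 8 of 10 genes, with a median of 0.39 (camera adjusted p = 0.137), led by the shikimate kinase SK2 with 1.15 ± 0.45 and the pathway's entry enzyme DAHPS1 with 0.88 ± 0.48. Leaving out mock 2 gave 0.19 for that median, 0.72 for SK2 and 0.34 for DAHPS1.

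Salicylate signalling genes were lower in 13 of 18 cases, with a median log2 fold change of -0.36 (camera adjusted p = 0.137), and passed with no filter on dim probe sets (adjusted p = 0.0118). With the main filter and an estimated correlation the adjusted p was 0.729. The median was -0.22 without rust 3 and -0.24 without mock 3. NH1, the rice NPR1 gene, had a log2 fold change of 0.65 ± 0.32. Ethylene genes were higher in 12 of 19 cases, with a median of 0.07 (adjusted p = 0.623), or -0.06 with arrays centred on the median (0.734), and ERF25 and ERF24 had 1.91 ± 0.81 and -1.61 ± 0.73. ERF24 was low on rust 1 and rust 2, at 210 and 161, and at 1360 on rust 3. Without rust 3 it had -2.58 and without rust 2 -1.04, and ERF25 had 0.97 without mock 2. Receptor-like kinase genes were lower in 8 of 13 cases, with a median of -0.07 (adjusted p = 0.419). CEBIP, the receptor that binds chitin fragments, was below every mock array in all rust arrays, with a log2 fold change of -0.93 ± 0.23 (limma adjusted p = 0.679). Calcium signalling genes were lower in 43 of 77 cases, with a median of -0.06 (adjusted p = 0.590), and the calmodulin-like gene CML15 had -1.67 ± 0.44. Oxidative burst genes were lower in 9 of 17 cases, with a median of -0.07 (adjusted p = 0.590), and the peroxidase PRX112 had 1.09 ± 0.33. MAP kinase cascade genes were higher in 11 of 17 cases, with a median of 0.02 (adjusted p = 0.935), or -0.11 with centring (0.831). Cytochrome P450 genes were lower in 9 of 14 cases, with a median of -0.15 (adjusted p = 0.590). Among them CYP90A4, of brassinosteroid synthesis, had 1.63 ± 0.37 and did not pass (limma adjusted p = 0.672). Over the list alone its limma adjusted p was 0.0295, which does not account for the number of lists searched. The 5 glutathione S-transferase genes had a median of 0.07, with a test direction of down (adjusted p = 0.932), or -0.06 with centring (0.828). Leaving out 1 array turned the sign of the medians of these receptor-like kinase, calcium, oxidative burst, MAP kinase, cytochrome P450 and glutathione S-transferase lists.

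**Figure D3:**
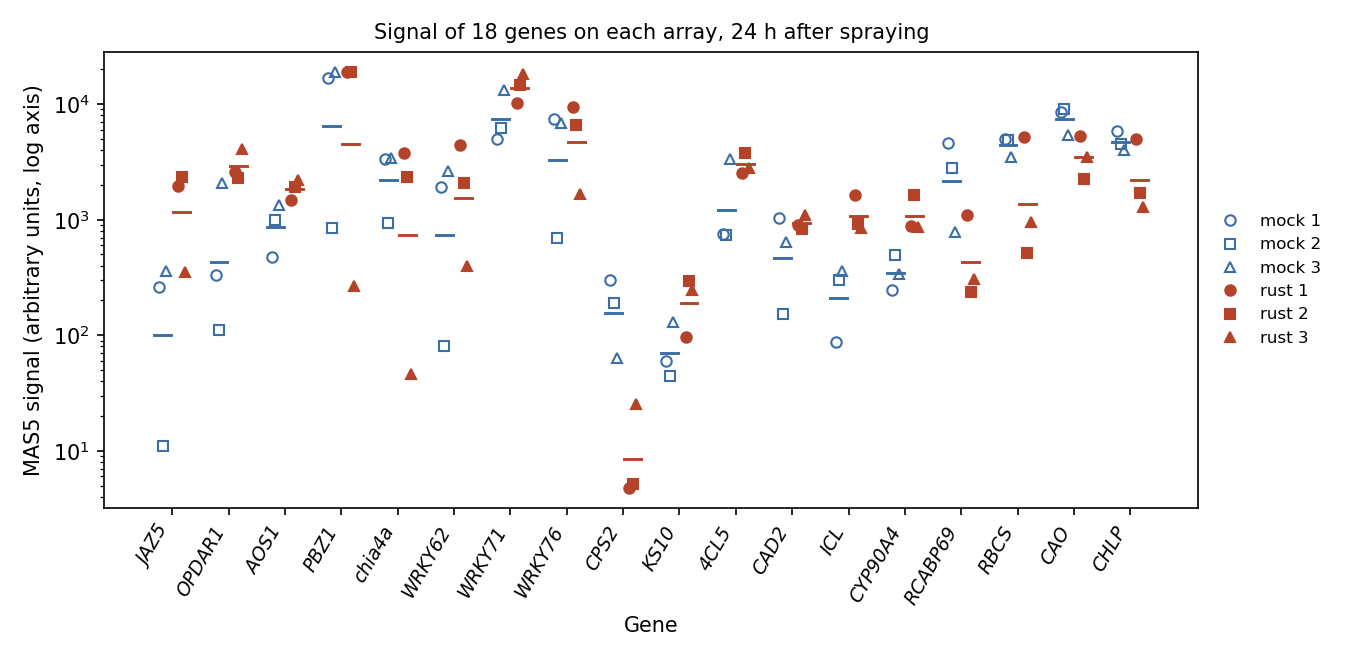
Signals of 18 named genes (horizontal axis) on the 6 arrays in MAS5 units on a log axis, with filled red symbols for rust, open blue symbols for mock and a bar for the mean of the log2 signals of each group. PBZ1 was at 265 on rust 3 and 854 on mock 2 and between 16960 and 18891 on the other 4 arrays, and ICL lay between 841 and 1634 after rust against 87.1 to 357 in mock.

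Senescence and starvation genes were higher in 9 of 16 cases, with a median log2 fold change of 0.14 (camera adjusted p = 0.590), or -0.01 without rust 1. ICL encodes isocitrate lyase of the glyoxylate cycle, which feeds carbon from fatty acids into sugars. Its log2 fold change was 2.36 ± 0.55 and did not pass (limma adjusted p = 0.672). Over the list alone the limma adjusted p was 0.0438, which does not account for the number of lists searched. SAG12, a senescence-associated protease gene, had 2.07 ± 0.70, or 1.55 with a pseudocount, from mock signals of at most 24.7. Heat shock and chaperone genes were higher in 25 of 45 cases, with a median of 0.04 (adjusted p = 0.590), which was below 0 after both other scalings, and the heat stress factor HSF07 had 1.84 ± 0.44. Genes of dehydration and abscisic acid were higher in 51 of 82 cases, with a median of 0.12 (adjusted p = 0.419), or -0.01 with centring (0.573) and 0.03 without rust 3. Cell wall expansion genes were higher in 26 of 40 cases, with a median of 0.26 (adjusted p = 0.399). Mock 2 set this sign too, since the median was -0.16 without it, with a test direction of down (adjusted p = 0.548), and it was 0.01 after quantile normalization. The expansin gene EXPA5 had 2.63 ± 1.03, with signals of 9.86 and 9.88 on mock 1 and mock 2, where the 25th percentiles were 7.26 and 9.50. The size of its fold is therefore not exact either, and with a pseudocount it was 1.98. The cellulose synthase-like gene CSLC9 had 1.85 ± 0.58, or 1.13 without mock 2. Nitrogen assimilation genes were higher in 10 of 18 cases, with a median of 0.23 (adjusted p = 0.935), or -0.02 without mock 2, while the glutamine synthetase gene GLN2 had -1.13 ± 0.40. Circadian clock genes were higher in 5 of 7 cases, with a median of 0.43 (adjusted p = 0.590), which ran from 0.17 without mock 1 to 0.77 without rust 1. The clock gene GI had 1.01 ± 0.46, or 0.67 without rust 2. The 9 lipid transfer and cuticle genes had a median of 0.00 (adjusted p = 0.932), or -0.13 with centring (0.933).

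Markers of other tissues did not pass either. Genes of dividing cells were higher in 11 of 21 cases, with a median log2 fold change of 0.01 (camera adjusted p = 0.711), root genes in 2 of 7, with -0.15 (0.590), and pollen and flower genes in 12 of 19, with 0.07 (0.590). The medians for dividing cells and for pollen and flower were below 0 after both other scalings, and the test direction of both was down. The root median was 0.13 without rust 2 and -0.52 without mock 3. The list of conserved eukaryotic genes such as tubulins and actins, whose probe sets RNA of the fungus might also bind, was higher in 16 of 21 genes, with a median of 0.16 (adjusted p = 0.379), or -0.02 without mock 2. It passed without rust 3 (adjusted p = 0.0336), and with all arrays and an estimated correlation the adjusted p was 0.795. The list of NB-LRR proteins held 1 measured gene, RPP13-1, with a log2 fold change of 0.09 ± 0.18, or -0.04 with centring. It was matched by symbol alone, which does not show that it encodes such a protein.

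The integrity of the RNA was read from the ratio of 3' to 5' control probe sets within each array. For actin it was 3.38 ± 0.31 (SD, n = 3) after rust and 6.19 ± 3.48 (SD, n = 3) in mock (exact two-sided permutation p = 0.4). For glyceraldehyde-3-phosphate dehydrogenase it was 2.92 ± 0.89 against 3.83 ± 1.94 (exact p = 0.7), and for cyclophilin 1.75 ± 0.19 against 2.18 ± 0.41 (exact p = 0.2). For ubiquitin it was 0.682 ± 0.017 against 0.771 ± 0.042 (exact p = 0.1), with every rust array below every mock array. With 3 arrays against 3 no p can go under 0.1, and after Benjamini-Hochberg adjustment over the 4 ratios the smallest was 0.4. All 4 mean ratios were lower after rust, beside the gene groups described above.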

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

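All the tests in this part except Fisher's test on the other genes of the stretches were chosen after the result they bear on was seen. A control probe set for elongation factor 1 alpha, Mgr-ef1a-3, lies outside the comparison of rice genes and had a mean signal of 34.8 ± 15.8 (SD, n = 3) after rust against 10.6 ± 3.61 (SD, n = 3) in mock, with every rust array above every mock array. It was 1 of 10 Mgr control probe sets to do so, where chance gives 5% each. Its signals were dim, near or below the array medians of 40.7 to 101. The lowest rust signal was 16.7, on rust 1, and the highest mock signal was 14.5, on mock 2.

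Rust 3 stood apart in its dim probe sets. Its 25th percentile was 29.9 against 7.26 to 10.7 on the other arrays. Rice transcripts present in this sample alone were argued against, because the 33 control probe sets with no rice target were higher there too, by a median of 2.47 on the log2 scale over the mean of the other 5 arrays. Rice probe sets of the same brightness were higher by a median of 2.12. Hybridisation background or noise on this array is a candidate explanation that these values fit, and it was found and tested on the same arrays.

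In the second pattern, PBZ1, chia4a and Cht4 were low on rust 3 and mock 2. The median deviation of the pathogenesis-related list was -2.11 and -1.40 on these arrays. Not every defence list shared this on rust 3. There the median deviation was 0.17 for WRKY, 0.21 for jasmonate and 0.14 for salicylate genes. It was -0.05 for diterpenoid and -0.18 for phenylpropanoid genes. On mock 2 it was -0.58 for WRKY, -0.56 for jasmonate, -0.53 for diterpenoid and -0.80 for phenylpropanoid genes, and 0.14 for salicylate genes. The WRKY list was as low on mock 1, at -0.60. WRKY62, WRKY76 and CPS4 of these lists were, like PBZ1, lowest on rust 3 and mock 2. On rust 3 and mock 2, 107 probe sets were lower than on the other 4 arrays by over 4-fold and 1 was higher. RNA degradation beyond that of all other arrays was argued against, since the 3' to 5' ratios of both arrays lay above the other 4 in 0 of 4 control genes. The highest ratio was on mock 1 for actin and ubiquitin and on mock 3 for the others, and PBZ1 was not low there. For glyceraldehyde-3-phosphate dehydrogenase rust 3 and mock 2, at 3.93 and 3.47, lay above every array but mock 3. Lesser damage is thus not excluded. Compression of bright signals stays open. The median difference over the brightest 3091 features was -0.058, but bright signals carry most of the trimmed mean to which each array is scaled. The scaling therefore holds such a median near 0. An exchange of labels between rust 3 and a mock array stays open: at most 2 of the 10 pathogenesis-related genes then had every rust array above every mock array, but with 2 low arrays against 4 no exchange of 1 pair could part the groups. The groups do not follow this pattern, so no biological explanation was tested.

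In the third pattern, rust 1 and rust 2 were parted from the other 4 arrays, with 11 probe sets higher and 28 lower in both by over 2 on the log2 scale. All 20 features that passed without rust 3 belonged to this set, of which 9 had exactly 1 gene and 6 of these lay in the stretches described next, while JAZ5 and ERF24 belonged to the set and lay outside them. Of its 21 genes with a place in the gene order of assembly ASM3414082v1, 16 lay within 50 genes of another of the set. In 10000 random draws the mean was 2.17 and the highest value 12 (permutation p = 0.0001, the smallest these draws can give, 0.0008 adjusted over 8 sets). This argues against an inoculation response that rust 3 lacked and that lay wholly scattered over the genome. A scattered part beside the clustered one stays open, since the test took the placed genes as 1 set. In the 2 stretches that held at least 4 genes of the set, with 4 and 7 of them, 16 of 126 other genes were parted the same way by over 0.5, against 473 of 15522 elsewhere (Fisher's exact one-sided p = 1.95e-06, with genes that are not independent). The plants of rust 1 and rust 2 may have carried another haplotype in a few chromosome regions, a hypothesis found and tested on the same data, and a response of neighbouring genes to the rust stays open.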

How the results depend on the processing

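Every alternative here was planned before the data were examined, and the splits of the arrays were read after the results were seen. The count of 0 genes held under every alternative but those that leave out an array, where it ran from 0 to 20, with 0 to 1 higher (1 without rust 3 and without mock 2) and 0 to 19 lower (all 19 without rust 3). The count of 4 lists became 1 with centring on the median, 2 with a pseudocount, 1 without trend, 3 with array weights, 2 with the mean of probe sets, 3 without those ending in x or s, 3 with the replicate block, 0 with an estimated correlation, 0 with fry, and 0 to 4 with an array left out. Of 18 alternatives the jasmonate list passed in 15 (adjusted p 1.68e-07 to 0.729), chlorophyll in 8 (0.000930 to 0.729), protein folding in 7 (0.000860 to 0.795), ribosomal proteins in 7 (0.000518 to 0.795), photosystems in 4 (0.00148 to 0.729) and the WRKY list in 0 (0.0518 to 0.729). None of these lists passed with an estimated correlation or with fry, so every pass kept the preset correlation of 0.01. The estimated correlation was 0.28 for jasmonate, 0.26 for chlorophyll, 0.24 for protein folding and 0.38 for ribosomal proteins. The salicylate list passed with no filter (0.0118) and the conserved eukaryotic list without rust 3 (0.0336). Besides these and photosystems no list gained a call. With a robust prior, camera gives no list value of its own, and without gene collapse none was computed.

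Of 1124 values of the 67 genes, 1105 kept their direction, 0 passed the threshold and 19 reversed, in 12 genes. After quantile normalization CPS4 had -0.12, and with centring the log2 fold change of RPP13-1 was -0.038. With array weights, which gave rust 3 a weight of 0.314, PBZ1 had 0.43, PRR37 0.12 and GST1 -0.047, and the pathogenesis-related list turned up (adjusted p = 0.809). With an array left out that list ran from 0.0989 to 0.920 and was up without rust 3, mock 1 or mock 3. The log2 fold changes then ran from -1.98 to 1.54 for PBZ1, -2.76 to 0.42 for chia4a, -2.11 to 0.33 for Cht4, -1.78 to 0.028 for CHI and -1.25 to 0.32 for PRR37, all positive only without rust 3 save PBZ1. Without mock 2 the low ends were reached in the ranges -0.55 to 2.03 for WRKY62, -0.61 to 1.25 for WRKY76, -0.92 to 1.09 for CPS4, -0.22 to 0.58 for GST1, -0.044 to 1.90 for the gene called peroxidase and -0.035 to 0.77 for UBQ2. The cause was not tested beyond the array left out.

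The labels do not say whether the replicate numbers pair the samples. Same-numbered arrays deviated from their groups with correlations of 0.25, -0.16 and 0.06, and so few arrays cannot exclude a shared day or batch. The replicate block gave 0 genes and 3 lists, losing protein folding (adjusted p = 0.0802) and ribosomal proteins (0.126) and adding photosystems (0.0205). Of the 10 splits of the 6 arrays, 10 gave at least the real 0 genes (highest other 1) and 5 at least the real 4 lists (highest other 9, with rust 1, rust 2 and mock 3 together). These splits are too few for a share under 0.05. If the higher dim signals of rust 3, whose median signal was 101, are background, they limit its dim genes.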

Other observations

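The genes and the control counts in this part were chosen after their values were seen. The 6 genes named here were among those with the smallest p outside the lists, and none passed. DXPS, which encodes the first enzyme of the plastid isoprenoid pathway, was at 409, 635 and 361 after rust and at 109, 79.1 and 71.1 in mock. Its log2 fold change of 2.42 ± 0.37 did not pass (limma adjusted p = 0.393). NSHB2, a non-symbiotic haemoglobin gene, was at 500, 899 and 829 after rust and at 154, 34.5 and 197 in mock, with a log2 fold change of 2.83 ± 0.65 (limma adjusted p = 0.672). The cytokinin oxidase gene CKX4 and the sucrose synthase gene SUS4 had log2 fold changes of 1.04 ± 0.23 and 0.87 ± 0.21, with every rust array above every mock array. SNAT2, with -2.06 ± 0.44, and KRP1, with -0.77 ± 0.19, lay below every mock array on all rust arrays.

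Of the 123 control probe sets, 14 lay above all mock arrays on every rust array and 2 below, where chance gives 5% each way. Of the 23 rice control probe sets bright enough to be tested, 10 lay above and 0 below. These 10 belong to 4 genes, with 4 for actin, 3 for cyclophilin, 2 for ubiquitin and 1 for glyceraldehyde-3-phosphate dehydrogenase, so they are not independent.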
